A study of Caenorhabditis elegans with 4 samples.

How the data were processed

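Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans hermaphrodites at the L2 larval stage. The strain carried an integrated transgene that expressed NHR-12, a member of the nuclear hormone receptor family of transcription factors, fused to EGFP. The labels list 4 samples in 2 groups, with 2 anti-GFP ChIP libraries and 2 matched input libraries, each numbered as replicate 1 or 2. Per the labels' protocols, animals were grown at 20 °C, crosslinked with 2% formaldehyde and quenched with 100 mM Tris. Chromatin was sheared by sonication, 10% of the lysate (or a fixed volume of it) was kept as input, and the rest was precipitated with anti-GFP antibodies. The labels do not say whether the replicates came from separate cultures, so differences between them can be technical. No region list of an input library was analysed here.

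The authors deposited 3 lists of binding regions, namely 1 for each ChIP replicate and 1 for both replicates combined. Per the file headers, positions are on genome build WormBase WS220. The source column of the deposited lists reads spp_via_IDR, which names the SPP peak caller and the irreproducible discovery rate (IDR) procedure that ranks regions by agreement between replicates. The aligner, the versions, the thresholds and the use of the input libraries are not given in the sources used here. Each region has a start, an end and a score that the authors' caller assigned. The files do not state the scale of the deposited score. Its values have the range of −log10 of a false discovery rate. Read that way, the lowest score of the combined list would be a rate of 0.0501, while the median scores of replicates 1 and 2 would be rates of 0.74 and 0.884, so that most entries of the replicate lists would be relaxed calls and not binding sites at a strict threshold. It was used only to rank or filter regions within a list, with a higher score taken as stronger. The highest score was shared by 363 regions of replicate 1, 75 of replicate 2 and 102 of the combined list. Ties in a replicate list were broken by the number in the region's name, and ties in the combined list by the mean percentile rank of the overlapping regions in the 2 replicate lists. The lists hold no read counts, so sequencing depth is unknown and no value could be weighted by it.

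The processing sets several properties of the lists. Widths are fixed for nearly all regions (600 bp in replicate 1, 516 bp in replicate 2 and 564 bp in the combined list), so width carries little information on the extent of binding. The replicate lists are long and cover 13.2% and 14.1% of the nuclear chromosomes, so many regions overlap between them by chance. The list of replicate 2 holds exactly 30000 regions, and whether its length was capped is not given in the sources used here. Overlap shares and the weakest rank bins depend on where each list ends. Some regions overlap others of the same list. The combined list was made from both replicates, and its overlap with them is not independent evidence.

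Overlap was counted at 1 bp or more. The chance level was taken from 10000 circular shifts, in which all regions of a chromosome move by 1 random offset and keep their widths and spacing. The smallest two-sided p these shifts can give is 0.0002. Chromosome lengths were taken as the largest region end in the 3 lists, since no genome sequence of build WS220 was used here. Shares per chromosome and in the middle 50% of the 5 autosomes were compared with length by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over the 6 nuclear chromosomes. Intervals are 95% exact binomial (Clopper-Pearson). They cover counting error over regions, which are not biological replicates. A rank correlation was computed across regions paired by mutual best overlap, with an interval from 1000 resamples of pairs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. Overlap counts were checked against bedtools 2.31.1 and were identical for the 4 pairs of lists. On simulated lists of 25045 and 30000 regions, with 20% of the first given a partner in the second, the overlap in excess of the shifts gave back 19.9%. With no partners planted, the excess was -0.46%. Of 1000 uniformly placed lists of the combined size, 5.1% were called for chromosome X at 0.05.

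Tests, alternatives and the rule for naming regions were fixed before the data were examined, except where stated. The rule named the genes of the 25 strongest combined regions, and fell back on position where no annotation of the build could be used. The gene table given for this work is of assembly WBcel235 and not WS220. Its coordinates were therefore not used, and regions are named by position. For the same reason the planned comparisons with gene starts, exons and introns, fixed gene lists, gene biotypes and the nhr-12 and unc-119 loci were not run. The gene table served only to count protein-coding genes per chromosome in WBcel235. Alternatives covered the overlap criterion, stricter thresholds, the number of top-ranked regions, lists from 1 replicate alone, other reference shares, merging of regions within 1 kb and shifts limited to 5 to 100 kb.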

Results

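NHR-12::GFP binding regions were mapped by anti-GFP ChIP-seq in L2 larvae of C. elegans, in 2 ChIP replicates with matched input libraries. The question stated for the series was where in the genome NHR-12 binds at this stage. The combined list held 197 regions, the list of ChIP replicate 1 held 25045 and the list of ChIP replicate 2 held 30000. All 197 combined regions lay on the 6 nuclear chromosomes and together covered 0.107 Mb, or 0.106% of their length. The replicate lists covered 13.2 Mb and 14.1 Mb. The combined regions had a median width of 564 bp and ranged from 141 to 2979 bp, with 180 of them at exactly 564 bp. Read depth was unknown for all libraries. All positions are on WS220, and scores are the authors' own.

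The highest score of the combined list, 2.37, was shared by 102 regions. The 25 of these with the best mean rank in the 2 replicate lists are named here, so their high ranks in the replicates follow from the selection. In replicate 1 the overlapping regions of all 25 shared the list's highest score, as did those of 24 in replicate 2, so their order rests on the numbers in the region names. Other regions with the same score ranked as low as 15631 of 25045 in replicate 1 (III, from 12425581 to 12426885), and 2 on IV had no counterpart in replicate 2. The first of the 25 was on chromosome III, from 3867391 to 3867692, and ranked 8 in replicate 1 and 3 in replicate 2. The second was on IV, from 654799 to 655066, with ranks 14 and 4. The third was on I, from 13475558 to 13475788, with ranks 19 and 9. It was followed by a region on III from 12904820 to 12905383, with ranks 18 and 12. The next, on X from 14525644 to 14525956, had ranks 15 and 21. Another X region, from 11093763 to 11094326, had ranks 36 and 7. A region on II from 10563385 to 10563623 had ranks 17 and 30. A further X region, from 5841021 to 5841584, had ranks 32 and 16.

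The rest of these 25 regions are given by their starts. On III they started at 10759045, 7854357 and 4475362. On II a region of 2979 bp, the widest of the combined list, ran from 8418663 to 8421641. On X they started at 11937239, 16056227, 9465709, 5801107, 12362861 and 4208956. On I they started at 13463818, 9625788, 13663028, 4172067 and 7475054. One region on V started at 10897254 and one on IV at 4749980. In all, 9 of the 25 were on X, 6 on I, 5 on III, 2 on II, 2 on IV and 1 on V. Genes at these positions were not assigned, because an annotation of the same build was not used here.

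**Figure D1:**
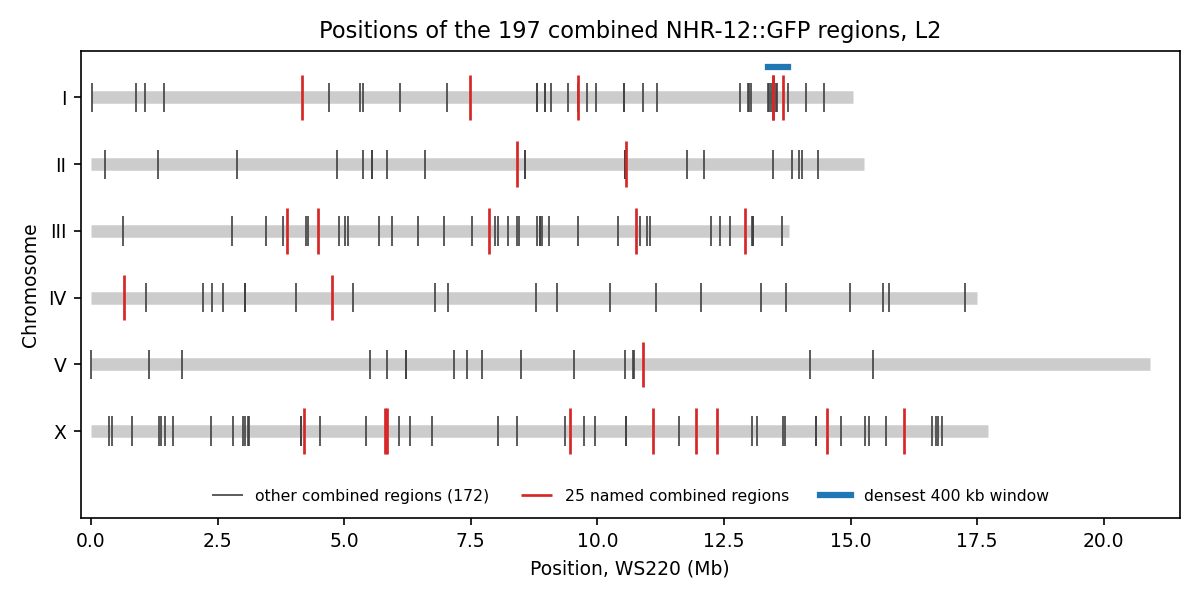
Positions of the 197 combined regions along the 6 nuclear chromosomes of WS220, in Mb. Each vertical line is 1 region, red lines are the 25 named above, whose top score 77 other regions share, grey bars run to the largest region end, and the blue bar marks the window of 400 kb that held the most regions, on I from 13372777 to 13756829. Chromosome V carried 18 regions and X carried 51.

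The next comparison asked how the combined regions related to each replicate. Of the 197 combined regions, 191 overlapped a region of replicate 1 (97.0%) and 193 overlapped a region of replicate 2 (98.0%), and 187 overlapped both. Shifted combined regions met the lists at 23.9% and 27% on average. The overlapping regions had a median rank of 176 in replicate 1 and 130 in replicate 2. The top 197 regions of replicate 1 accounted for 102 of the combined regions, and those of replicate 2 for 131. Another 26 combined regions met nothing stronger than a region below the top 10% of replicate 1, against 7 in replicate 2. The 6 combined regions with no counterpart in replicate 1 started at 5373165, 14349271 and 13976012 on II, at 6447574 on III and at 12036960 and 7048118 on IV. Of the 4 with none in replicate 2, 3 formed a single locus on IV from 3050199 to 3051188, which ranked 99 in replicate 1. The other was on X, from 3127553 to 3128116, and met only rank 13102 in replicate 1.

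The 2 ChIP replicates marked the same places more often than chance, both at the top of the lists and throughout them. In replicate 1, 11055 of 25045 regions (44.1%) overlapped a region of replicate 2, against 28.0% under circular shifts. In replicate 2, 10868 of 30000 regions (36.2%) overlapped replicate 1, against 23.0% under shifts. Both were 1.57 times the chance level, with a two-sided p of 0.0002 by the shift permutation test, the smallest the shifts can give. Among the strongest 10% of each list the overlap was 59.6% (95% interval 57.6 to 61.5) in replicate 1 and 50.2% (48.4 to 52.0) in replicate 2. Among the weakest 10% it was 39.9% (38.0 to 41.8) and 29.9% (28.3 to 31.6), against 27.9% and 22.9% under 1000 shifts. With midpoints required to lie within 100 bp, 15% of replicate 1 and 12.5% of replicate 2 matched, against 6.08% and 5.06% under shifts. The overlap stayed above the shifts in all 10 rank bins of both lists, with a two-sided p of 0.002 in each by the shift permutation test, the smallest these shifts can give.

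**Figure D2:**
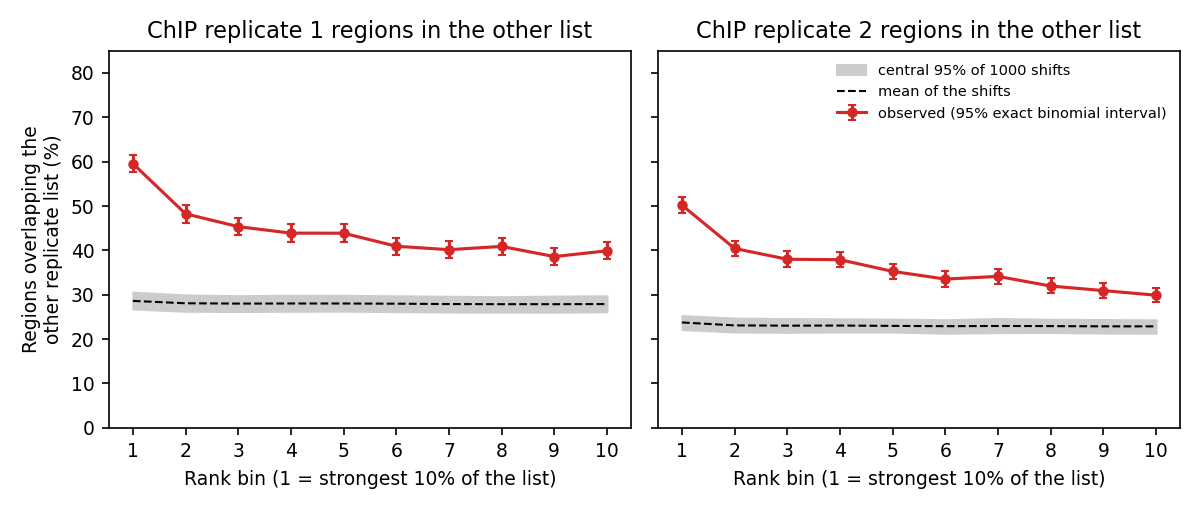
Share of regions (%, y axis) of each ChIP replicate that overlapped the other replicate's list by 1 bp or more, in 10 rank bins from strongest to weakest (x axis). Points are observed shares with 95% exact binomial intervals, dashed lines the mean of 1000 circular shifts and grey bands the central 95% of the shifts. The share fell from 59.6% in the first bin of replicate 1 to 39.9% in its last, and lay above the band in every bin of both lists.

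At equal list lengths, 86 of the top 197 regions of replicate 1 (43.7%) overlapped the top 197 of replicate 2, where shifts gave 19.1 (two-sided shift permutation test, p = 0.0002). Mitochondrial regions made up 19 and 16 of these top regions and nearly all of the chance overlap. With nuclear regions alone, an alternative chosen after the data were seen, 71 of 197 (36.0%) overlapped and shifts gave 0.494 regions (same permutation test, p = 0.0002). In replicate 1, 344 nuclear regions shared the highest score, so its top 197 are set by the number in the region name. Among the nuclear top 197, 28 regions of replicate 1 and 29 of replicate 2 overlapped neither the other replicate's full list nor the combined list. The first of these in rank order was on V from 5049227 to 5049826 in replicate 1, at rank 21 among the tied regions. In replicate 2 it was on V from 9344115 to 9344630, at rank 55. Across 8941 pairs of shared regions the ranks in the 2 lists had a Spearman rho of 0.13 (95% interval 0.11 to 0.15). Where both partners came from the weaker 50% of their lists, rho was 0.01 over 1965 pairs. These correlations are across regions, which are not independent replicates. Part of the pairs overlap by chance, since shifts gave 28.0% of replicate 1 against 44.1% observed, and such pairs can lower rho. Keeping only the weaker 50% narrows the range of ranks, which can also lower rho. The values are therefore no measure of how strengths compare at sites that both replicates share.

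The combined regions were not spread over the chromosomes in proportion to length. Chromosome V held 18 of 197 regions, or 9.14% (95% interval 5.51 to 14.1), with 20.9% of the nuclear length, which is 0.438 times the number given by length (exact binomial test, adjusted p = 8.63e-05). Chromosome X held 51, or 25.9% (19.9 to 32.6), with 17.7% of the length, a ratio of 1.46 (exact test, adjusted p = 0.0111). Chromosome III held 41, or 20.8% (15.4 to 27.2), with 13.8% of the length, a ratio of 1.51 (exact test, adjusted p = 0.0135). Chromosomes I, II and IV did not pass the test, with 40, 23 and 24 regions and adjusted p of 0.0679, 0.197 and 0.0717. Of the top 197 nuclear regions of each replicate alone, 109 in replicate 1 and 134 in replicate 2 overlapped the combined list. Calls kept in these top lists are therefore not independent evidence. In them, V held 22 in replicate 1 and 20 in replicate 2 (exact test, adjusted p = 0.00129 and 0.000599). The call for X was lost in both, with 46 and 39 regions (exact test, adjusted p = 0.060 and 0.545). Chromosome III kept its call in both, with 46 and 40 regions (exact test, adjusted p = 0.00129 and 0.025). Chromosome IV passed as low in both, with 20 and 22 regions (exact test, adjusted p = 0.0124 and 0.028). Chromosome I passed as high in replicate 2 only, with 44 regions (exact test, adjusted p = 0.0201). In the stronger 50% of the combined list the ratio for III was 1.56, with 21 of 98 regions, and the call was lost at this smaller number of regions (exact test, adjusted p = 0.0702). All 98 lie among the 102 regions tied at the highest score, so mean rank in the replicates set this cut.

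The replicate lists in full were closer to the length share on V, with 19.1% of the nuclear regions of replicate 1 and 19% of those of replicate 2, and still below it (exact binomial test, adjusted p = 2.45e-12 and 1.61e-15). Chromosome X held 20.0% and 19.4%, above its length share in both (exact binomial test, adjusted p = 3.28e-20 and 3.07e-14). Chromosome IV held 18.5% and 20.9%, above its length share of 17.5% (exact test, adjusted p = 2.50e-05 and 5.90e-51), where the combined list had 12.2%. These tests on the full lists count each entry as independent. Merging overlapping entries would leave 19283 of 25045 regions in replicate 1 and 24400 of 30000 in replicate 2, so these p-values are too small. Against the replicate 1 share, chosen as a reference after the data were seen, X remained above with an adjusted p of 0.0487 and V below with 0.00107 (exact binomial test). Against the replicate 2 share these were 0.0296 and 0.00107. Chromosome IV lay below the shares of replicates 1 and 2 (exact test, adjusted p = 0.043 and 0.00614). Chromosomes I (0.0487 and 0.0296) and III (0.0302 and 0.0137) lay above both by the same test. On I, 9 of the 40 combined regions lay within 1 stretch of 384 kb, described below.

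**Figure D3:**
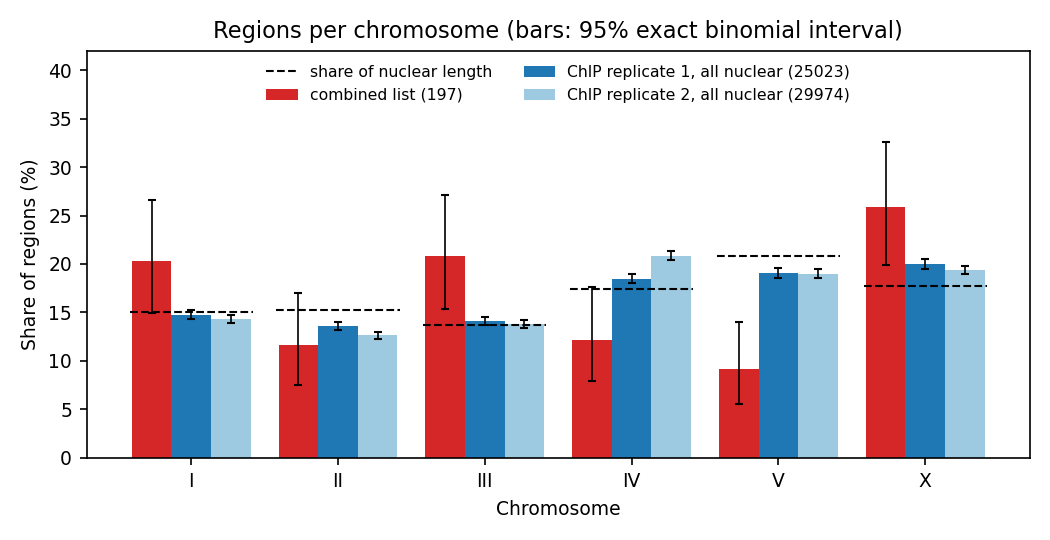
Share of regions (%, y axis, from 0) on each nuclear chromosome (x axis) in the combined list and among all nuclear regions of the 2 ChIP replicates, with 95% exact binomial intervals. Dashed lines give each chromosome's share of the nuclear length. The combined list had 9.14% on V, where length gives 20.9%, and 25.9% on X, where length gives 17.7%.

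Within the autosomes, 84 of 146 combined regions (57.5%, 95% interval 49.1 to 65.7) had their midpoint in the middle 50% of the chromosome. This did not differ from 50% by the exact binomial test (p = 0.0819). Chromosome V had 15 of its 18 regions there (83.3%, 58.6 to 96.4), with an adjusted p of 0.0377 over the 5 autosomes by the same exact test. With regions within 1 kb counted once, chosen after the data were seen, it was 14 of 17 and the call was lost (exact test, adjusted p = 0.0636). The other autosomes ranged from 9 of 24 on IV to 26 of 41 on III and did not pass. In the top 197 nuclear regions of each replicate alone the middle share passed the exact test, with 62.9% in replicate 1 (p = 0.00189) and 58.2% in replicate 2 (p = 0.0464). All autosomal regions of the replicate lists gave 52.9% and 48.7%.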

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

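The mitochondrial chromosome entered no comparison between chromosomes and had no region in the combined list, yet both replicate lists held regions on it. There were 22 in replicate 1 and 26 in replicate 2. The replicate lists hold 25045 and 30000 regions against 197 in the combined list, so these raw counts do not test its count of 0. The 22 regions of replicate 1 had 6 distinct positions, covered 95% of the mitochondrial extent of 13419 bp and took 11 of the first 12 ranks. The 26 regions of replicate 2 had 18 distinct positions, covered 67.1% and took 3 of the first 12 ranks. Repeated entries at 1 position were thus counted more than once in the replicate lists. No cause was tested.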

How the results depend on the processing

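The alternatives for lists without mitochondrial regions or regions of the combined list, for merged regions, for shifts of 5 to 100 kb and for shares of the replicate lists were chosen after the data were seen. The overlap between replicates stayed above chance under every alternative run, and no called result reversed. Its size depended on the rule: with midpoints within 100 bp it fell from 44.1% to 15% in replicate 1, from 36.2% to 12.5% in replicate 2 and from 43.7% to 25.9% among the top 197. The same rule lowered the share of combined regions found in replicate 1 to 88.3% and raised the rank correlation from 0.13 to 0.187, over 3759 pairs in place of 8941. The share of combined regions on X, 25.9%, came to between 19.8% and 23.4% in lists built without 1 replicate and no longer passed the test, whereas V kept its call in both. The share in the middle of the autosomes, which did not pass in the combined list, came to between 58.2% and 62.9% in those lists and passed. It also passed against the share of replicate 2 (57.5% against 48.7%, p = 0.0381 by the exact binomial test), and not against that of replicate 1 (p = 0.282). The high middle share on V lost its call with regions merged, in the stronger 50% and in the list without replicate 2, and kept it without replicate 1. The share itself hardly moved with regions merged (14 of 17, 82.4%) and in the stronger 50% (5 of 6, 83.3%), on fewer regions. Without replicate 2 it was 72.7% (16 of 22). The cause of these changes was not tested. Against protein-coding genes per chromosome in WBcel235, the shares on III, X and V kept their direction and calls. Chromosome III kept its call under the other alternatives too, except in the stronger 50% of the combined list. Across the alternatives for I, II and IV, 9 brought a call on I, II or IV that the main test did not give. On IV the calls were low, in both lists built without 1 replicate and against both replicate lists in full. On I they were high, without replicate 1, against gene numbers and against both full lists. The call on II was low, against gene numbers. Without a call, IV still lay below its reference share in the stronger 50%, with regions merged and against gene numbers. The median width of 564 bp became 516 and 600 bp in the lists of replicates 2 and 1, which follows from their fixed widths. No paired analysis was possible because the comparisons use ChIP lists only and no list of an input library was analysed here. The planned use of summits was not run, since the lists give none, and neither were the planned comparisons with genes. The lists end at different lowest scores, 1.3 in the combined list against 0.00432 and 0.0204 in replicates 1 and 2. The scale of the score is not stated and the highest scores differ too (2.37, 2.86 and 2.17), so these lowest scores may not be comparable between lists. List lengths cannot be read as depth. Read depth is unknown, and any part it had was not tested.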

Other observations

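The tests of the window on chromosome I, of the replicate lists as reference for X and V and of region widths were chosen after the results were seen. The combined list held 9 loci of 2 or more regions within 1 kb of each other, with 19 regions in all. The one with most members, 3, was on IV from 3050199 to 3051188. Pairs lay on I from 8962673 to 8963463 and from 10516695 to 10517476, on II from 5543425 to 5543988 and from 10550382 to 10552288, on III from 8873916 to 8874699 and from 13069896 to 13070804, on V from 6224419 to 6225342 and on X from 14312290 to 14313065. A width other than 564 bp was found in 11 of the 25 combined regions named by rank (44%) and in 6 of the other 172 (3.49%, Fisher's exact test, two-sided p = 1.09e-07). Both the pattern and the 25 come from these same lists, and the order of the 25 rests on the numbers in the region names. The p therefore describes the listing, and no link of width with binding was tested.

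The first pattern weighed is the high count of combined regions on X and the low count on V. Counting neighbouring regions more than once is not enough to account for it: with regions within 1 kb merged to 187 loci, X held 50 and V held 17, and the larger of the 2 exact binomial p was 0.00203. Gene number per chromosome does not account for it either, since V has 25% and X 13.7% of the protein-coding genes in WBcel235 (larger exact p = 5.66e-06). The spread of all called regions leaves the low count on V in place (larger exact p = 0.000179), but for X it stays open: the exact p against replicate 1 was 0.0406, the interval for X starts at 19.9% and the replicate 1 share is 20.0%. In the top regions of replicate 2 alone X held 19.8% (exact p = 0.455), and in those of replicate 1 it held 23.4% (exact p = 0.04, adjusted 0.06), so whether X is preferred may depend on how regions are selected. The low count on V and the high count on III (20.8% of the combined list, ratio 1.51) kept their adjusted calls in those lists. Many regions of those lists are also in the combined list, so this is not independent evidence. No biological explanation was tested. The planned comparisons with genes were not run, because no annotation of the same build was used, and the design has no second ChIP condition.

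The second pattern is that replicate regions outside the combined list still overlapped between replicates, in 43.6% of replicate 1 and 35.7% of replicate 2. An uneven density of calls along the chromosomes was tested with shifts of 5 to 100 kb, which keep that density over stretches longer than the shift. Unevenness over shorter stretches is not covered by this test. These gave 28.4% and 23.4%, and the observed shares lay above all of them (two-sided shift permutation test, p = 0.0002, the smallest the shifts can give). The recurring regions outside the combined list may be NHR-12 sites or background that both libraries share, such as accessible chromatin. These cannot be separated without the input libraries or a ChIP of an untagged strain, neither of which was analysed here.

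The third pattern is a group of 9 combined regions on I within 384 kb, from 13372777 to 13756829, where a window of 400 kb on that chromosome holds 1.01 loci on average. Uniform placement gave as many in some window in 17 of 10000 draws (permutation p = 0.0018). The fullest window of a draw held 5 loci at the median and 10 at most. A first check of dense calling there, set before the densities were seen, asked for under 1.5 times the chromosome mean in both lists. Replicate 2 missed that bound with 1.52 (replicate 1 had 1.18), and the check was then replaced by drawing loci from each replicate list at its own density. The larger p of the 2 lists was 0.0014 by these draws, whose fullest windows also held 5 loci at the median and 10 at most. The window test was chosen after the results were seen. Neither set of draws allows for a choice of window width, so both p can be too small. The top 197 nuclear regions alone placed 7 loci there in replicate 1 and 6 in replicate 2. The combined list was made from these replicates, so the 2 counts are not independent evidence for the group. A cluster of NHR-12 sites, a repeated sequence or extra copies of this segment in the strain are candidate explanations that remain untested, and 3 of the 9 regions were among those narrower than 564 bp.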
